A study of Mus musculus with 33 samples.

How the data were processed

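The series covered 33 samples of mouse endothelial cells: 13 RNA-seq libraries, 14 ATAC-seq libraries, 4 H3K4me1 ChIP-seq libraries and 2 ChIP input libraries. ATAC-seq reads out open chromatin through transposase insertion, and H3K4me1 is a histone mark found at enhancers and around promoters. Per the labels, cells were sorted as negative for CD41, CD45 and Ter119, positive for CD31 and VE-cadherin, and low to positive for cKIT, from whole embryos at E9.5, whole fetuses at E13.5 and livers of adults aged 4 to 6 weeks. RUNX1, the transcription factor required for blood formation from endothelium, was overexpressed from a conditional knock-in allele (CKI) in the presence of Cre. The group 1Runx1 carried Cre with 1 knock-in copy and 2Runx1 carried Cre with 2 copies. Ctrl carried knock-in alleles, and its labels name no Cre, so the presence of Cre and the added Runx1 copies coincided in every comparison with Ctrl. Females received 2 mg tamoxifen, 24 hours before harvest for the embryonic stages and by oral gavage at an interval not given in the sources used here for the liver. The background was a mix of C57BL/6J and 129Sv/J, with B6C3F1 added at E9.5, and the E9.5 matings used superovulated females.

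RNA-seq groups held 2 libraries each, except E13.5 Ctrl, which held 1. ATAC-seq held 2 libraries in each of 7 groups. H3K4me1 was measured in E13.5 Ctrl and 2Runx1, with 2 ChIP libraries and 1 input each. The labels do not say that replicates came from separate animals or litters, so the p-values measure only the spread between these samples, which may be technical. In the H3K4me1 2Runx1 samples the descriptions of the input and of 1 ChIP library appear to be exchanged, because the input's description names the enriched track and its peaks. The H3K4me1 2Runx1 regions were therefore read as those of the ChIP, and this assignment remains in doubt.

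Gene expression was deposited as 1 table of RPKM (reads scaled to gene length and library size), which the authors made from reads trimmed, aligned and counted with tools named in the submitters' processing notes without their order: bcl2fastq 2.20, FastQC, Trim Galore 0.6.4, STAR 2.7.3a, Subread 2.0.0, featureCounts and edgeR. The library kit, which fragments cDNA with a transposase, does not mark strand, so reads of a gene and of an antisense or embedded partner could not be told apart. Peak lists were deposited as MACS2 output, with Bowtie2 2.3.5.1, SAMtools 1.1, MACS2 2.1.4 and deepTools 3.3.0 named in the submitters' processing notes, and with mm10 and GRCm38 named as builds. The authors' peak lists give for each peak a display score (10 times −log10 q), a fold enrichment (a ratio over background) and −log10 q values; −log10 p values were not used here. Each ATAC-seq group and each H3K4me1 group had 1 list that combined its replicates, so peaks had no replicate check, and no test across replicates was made on them. Whether the authors shifted ATAC-seq reads for the transposase is not given in the sources used here. Scores and q values were used only to rank or describe peaks within a list.

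The RPKM values were whole multiples of what 1 read was worth. Whole reads that fitted the values were found for 100% of the 20720 genes with a value above 0, within a tolerance of 0.001 reads. A gene above 0 in only 1 library always passes this step. Counts with a common factor come back divided by it, so recovered reads can be too low. Of the simulated genes seen in all libraries, 98.4% were recovered exactly. The recovered totals were 37754246 to 44540403 reads per library. The RPKM values also held a scaling factor beyond the read total, between 0.83 and 1.13, lowest in the liver libraries and highest at E13.5. The table had 25239 genes, of which 4519 were at 0 in every library and 970 had no Ensembl identifier. No library was a duplicate of another: the SD of the log2 difference between replicates ran from 0.136 in E9.5 Ctrl to 0.246 in E13.5 1Runx1.

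Values were analysed as log2(RPKM + 1) for the 12546 genes with an RPKM of at least 1 in at least 2 of the 13 libraries. Fold changes are therefore on the log2(RPKM + 1) scale, which understates the change of low genes. Limma 3.58.1 in R 4.3.3 was fitted once to all libraries with 7 group means, moderated standard errors and an intensity trend. This gave 6 residual degrees of freedom, 4.3 prior and 10.3 in total. The single E13.5 Ctrl library was assumed to vary like the libraries of the other groups. Tests were two-sided, p-values were adjusted with the Benjamini-Hochberg method over the genes of each comparison, and genes were called at an adjusted p under 0.05. Unless another test is named, an adjusted p is limma's with this adjustment, an error after ± is the standard error for a fold change and the SD for an RPKM, and group means rest on 2 libraries. There were 10 RNA comparisons: each Runx1 group with the Ctrl of its stage, 2Runx1 with 1Runx1 at E13.5, the 3 pairs of Ctrl groups, and 2 interactions that compared effects between stages.

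On data simulated from the real genes with 100 genes changed by a log2 value of 0.5 and 100 by 1, the fit found 76% and 95% of them at E9.5, 59% and 88% for E13.5 1Runx1, 52% and 93% for E13.5 2Runx1, and 79% and 94% in the liver. Of 12346 unchanged genes it called 12, 5, 15 and 9. The simulation gave all libraries of a gene the same spread, which is what the fit assumes. In the real data the residual SD of a typical gene was 0.09 at E13.5 and 0.062 at the other stages. The simulated rates thus do not bound those of the real E13.5 comparisons.

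Before the data were examined, 27 gene lists were fixed, covering endothelial, blood and other cell types, TGFβ and BMP signalling, and general cell states. Each list with at least 5 genes measured was tested with camera in limma, with a preset correlation of 0.01 between genes and again with an estimated correlation, and adjusted over all lists and comparisons. Members called are given over all genes and adjusted over the list alone. Named genes followed a rule fixed at the same time: Runx1 first, then the 10 higher and 10 lower genes with the largest absolute fold change among those called whose libraries all lay on one side of the other group, leaving out predicted genes, Rik clones and pseudogenes. For stages and interactions 5 each way were taken, for each list described up to 4 members with the smallest p, and for peaks up to 5 members of 2 lists with the most gained peaks. A gene outside this rule is said to have been chosen after its values were seen.

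Peaks were compared with bedtools 2.31.1. A peak was shared where it overlapped a peak of the other list by at least 1 bp, gained where it was in the Runx1 list only and lost where it was in the Ctrl list only. Genes were placed with RefSeq positions on GRCm38.p6, found for 12494 genes (99.6%). The reference table gave no strand, so peaks were assigned to the gene body with 10 kb on both sides, in place of the planned span from 10 kb upstream to the gene's end. The alternative of 50 kb was likewise taken around the gene. A list's median number of peaks per gene was set against 10000 random lists of the same size matched on expression, as a description of these lists. The plan named no summary statistic for a list; the median was chosen and the mean was added as an alternative. No genome sequence was used here, so the planned search for RUNX motifs in peaks was not run.

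The alternatives tried were a pseudocount of 0.1, no expression filter, quantile normalization, median-of-ratios scaling, a fit of only the stages compared, no intensity trend, the replicate number as a block, each replicate left out in turn, a reciprocal overlap of 50%, equal numbers of top-ranked peaks, the stricter part of each list (the top 50% by score), and lists matched on gene length too. Added after the data were seen were limma-voom on the recovered reads, fry, a list of p53 target genes, the shared response of the 2 Runx1 groups at E13.5 with its alternatives, the mean of peaks, and gained peaks at called genes. Figures were drawn with Matplotlib 3.10.9 in Python 3.11.15.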

Results

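Endothelial cells sorted from mouse embryos at E9.5, fetuses at E13.5 and adult livers were profiled with and without added Runx1. RNA-seq covered 13 libraries of 37754246 to 44540403 recovered reads each, with 10779 to 11355 genes at an RPKM of at least 1. E13.5 Ctrl had 1 RNA library, and the other 6 groups had 2. ATAC-seq covered the same 7 groups with 2 libraries each, combined into 1 peak list per group. H3K4me1 regions were given for E13.5 Ctrl and 2Runx1. The series title names the accessibility of TGFβ target genes and hemogenic specification by RUNX1, and the comparisons asked how Runx1 changed RNA and open chromatin at each stage, whether copy number mattered at E13.5, and how the control endothelium of the 3 stages differed.

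Runx1 (ENSMUSG00000022952, chromosome 16, 92601466 to 92826074 on GRCm38) was higher in every library of the Runx1 groups than in every Ctrl library. At E9.5 its level was 0.910 ± 0.00756 RPKM in Ctrl and 15.6 ± 0.903 in 1Runx1, a 17.1-fold difference. At E13.5 it was 1.37 in the single Ctrl library, 26.3 ± 3.65 in 1Runx1 and 23.9 ± 1.75 in 2Runx1, or 19.2-fold and 17.5-fold. In the adult liver it was 1.36 ± 0.245 in Ctrl and 78.3 ± 0.173 in 2Runx1, 57.6-fold. On the log2 scale the differences were 3.12 ± 0.10, 3.52 ± 0.12, 3.39 ± 0.12 and 5.07 ± 0.10, with adjusted p of 1.16e-07, 1.76e-07, 7.68e-07 and 7.88e-10. The gain in the liver exceeded that of 2Runx1 at E13.5 by 1.68 ± 0.16 (adjusted p = 0.000102), whereas the gains at E13.5 and E9.5 with 1 copy differed by 0.40 ± 0.16 (adjusted p = 0.203). The table does not separate reads of the knock-in from those of the endogenous gene.

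**Figure D1:**
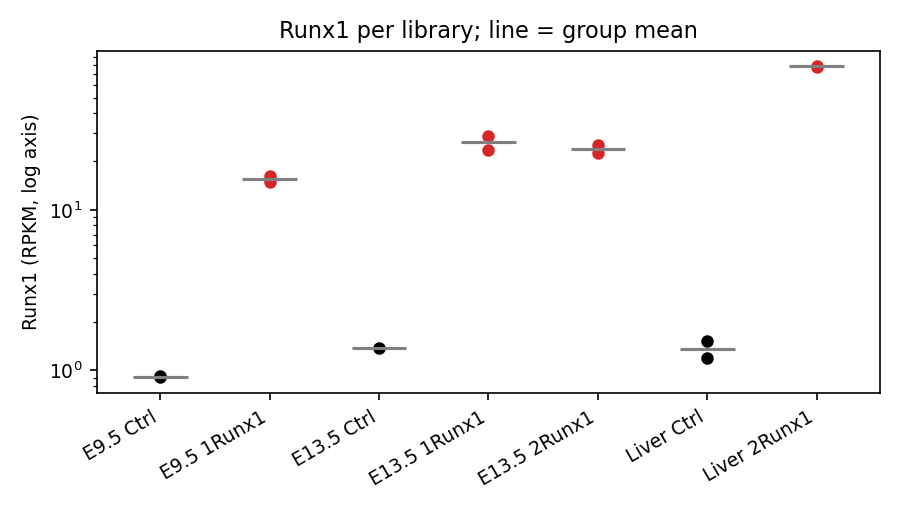
Runx1 level in RPKM (log axis) in each of the 13 RNA libraries, by group, with Ctrl in black, Runx1 groups in red and a line at each group mean. Every Runx1 library lies above every Ctrl library, and the liver 2Runx1 libraries are the highest at a mean of 78.3.

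At E9.5, the largest increases with 1 added Runx1 copy, after Runx1 itself, were in AI467606, Cdkn1a, Lgals9 and Itgb3. Cdkn1a, the cell cycle inhibitor p21 (chromosome 17, 29090979 to 29100722), rose by 2.25 ± 0.12 on the log2 scale, from 8.04 ± 0.628 to 42.1 ± 7.36 RPKM (adjusted p = 5.43e-06). Itgb3, integrin β3 of platelets and vascular cells (chromosome 11, 104608000 to 104670476), rose by 2.08 ± 0.11, from 1.06 ± 0.178 to 7.70 ± 0.0154 RPKM (adjusted p = 5.15e-06), and Lgals9, encoding galectin-9, by 2.11 ± 0.06 (adjusted p = 7.28e-08). Alox5 and Ltc4s, which act in leukotriene synthesis, rose by 1.93 ± 0.12 and 1.54 ± 0.14, and the transcription factor gene Stat4 by 1.95 ± 0.09. AI467606 (2.56), Tmem163 (1.53), Zfp365 (1.51) and Eda2r (1.5), a receptor gene of the TNF receptor family, completed the 10 largest increases, all with adjusted p of 0.00369 or less. Decreases were smaller: Ttc39c fell by 1.18 (adjusted p = 0.000328) and Dapk2, encoding a death-associated kinase, by 0.63 (adjusted p = 0.00326). Adat2 (−0.77), Gbp4 (−0.75), Rarres2 (−0.67) and Corin (−0.66) were called with adjusted p between 0.0243 and 0.0469. The small RNA genes Mir181b-2 (−1.68), Mir1931 (−1.57) and Snora30 (−0.97) were called too, but their reads may belong to overlapping host transcripts, and Fn3krp (−1.33) lay at the threshold.

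Of 12546 genes, 108 were higher and 41 lower in E9.5 1Runx1, 32 of them at least 2-fold, and 1508 had an unadjusted p under 0.05. The total of 149 was 37 in a fit of the E9.5 libraries alone, and 46, 41, 89 and 52 without Ctrl replicate 1, Ctrl replicate 2, 1Runx1 replicate 1 and 1Runx1 replicate 2. Of the 10 named decreases, Ttc39c and Dapk2 kept their calls with each of these libraries left out, while the other 8 lost theirs without 1 or more of them.

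Few members of the fixed gene lists changed at E9.5. Of 15 hemogenic and stem-cell regulators 0 passed over all genes, and Gata2 (0.37), a transcription factor of blood stem cells, was the 1 adjusted over the list alone; the list's median was 0.06, and camera gave adjusted p = 0.132. Of 26 TGFβ target genes 1 rose, Cdkn1a, both over all genes and adjusted over the list alone (median 0.00, camera adjusted p = 0.988). Among 21 TGFβ pathway components 0 passed over all genes and Smurf2 (0.29) alone adjusted over the list alone. Of 11 BMP targets, Atoh8 rose by 0.66 (adjusted p = 0.00916). Macrophage genes showed 3 of 18 higher, namely the Fc receptor genes Fcgr3 (1.33) and Fcer1g (1.08) and the lysozyme gene Lyz2 (0.53). Of 15 pan-haematopoietic genes 0 passed over all genes and Was (0.69) adjusted over the list alone. Of 24 endothelial identity genes, Sox7 rose (0.23) and Tek, the angiopoietin receptor, fell (−0.36), with 1 higher and 4 lower adjusted over the list alone, among them the VEGF receptor gene Kdr (−0.35) and Vwf (−0.50). Arterial and venous lists had medians of −0.13 and −0.18 (camera adjusted p = 0.0358 and 0.00282, or 0.448 and 0.461 with an estimated correlation). The 1 arterial gene past the test over all genes, Jag2 (0.48), was higher, and Gja4 (−0.26) and Sox17 (−0.32) were lower adjusted over the list alone. NF-κB genes moved both ways, with Nfkbia (0.51) higher and Tlr2 (−0.47) lower over all genes, and 4 higher and 2 lower adjusted over the list alone. The hepatocyte gene Trf (0.81) was higher and the brain endothelial gene Apcdd1 (−0.53) lower. Immediate early genes (median 0.36), glycolysis (0.11) and oxidative phosphorylation (0.07) lay higher, at camera adjusted p = 0.00177, 3.38e-05 and 0.00326, or 0.602, 0.3 and 0.407 with an estimated correlation. In those 3 lists Ier3 (0.64) and the hypoxia-induced hydroxylase gene Egln3 (0.62) were the members past the test over all genes.

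At E13.5, 1 added copy raised Cdkn1a, Stat4 and Ltc4s as at E9.5, and Afp, Alb and S100a9 were lower than in the single Ctrl library. Cdkn1a rose by 2.02 ± 0.15 (from 8.05 to 35.8 ± 5.71 RPKM, adjusted p = 5.47e-05), Stat4 by 1.87 ± 0.12, Ltc4s by 1.91 ± 0.18 and AI467606 by 1.85 ± 0.16. H2-K1, a classical MHC class I gene that can share reads with its family, rose by 2.25 ± 0.10, from 4.46 to 24.9 ± 0.878 RPKM (adjusted p = 1.99e-06), and Ttyh2, a chloride channel gene, by 2.00 ± 0.24. Mmp9, encoding a gelatinase, rose by 3.08 ± 0.71, but its 2 libraries were at 34.3 and 10.3 RPKM, and the difference was 2.26 with adjusted p = 0.0662 without the 1Runx1 replicate 1 library and had adjusted p = 0.138 with limma-voom. Afp and Alb, secreted by fetal liver cells, fell by 2.12 ± 0.17 and 1.79 ± 0.27, from 78.3 to 17.5 ± 3.58 and from 28.1 to 7.67 ± 3.01 RPKM. Serpina6, Rbp4, Ambp and Apom, further liver-secreted proteins, decreased by 1.77, 1.77, 1.75 and 1.64, the neutrophil gene S100a9 by 2.17, the platelet chemokine gene Ppbp by 1.88 and the metallothionein gene Mt2 by 1.56. Rbm45 was higher by 2.2 ± 0.44. Eno1b (chromosome 18, 48045335 to 48048379), a near-identical copy of the enolase gene Eno1 whose reads are uncertain, was higher by 3.67 ± 0.09, Gt(ROSA)26Sor, the non-coding gene of the Rosa26 locus, by 2.12 ± 0.13, while Cdk5rap1 was lower by −2.36 ± 0.15. For these 3 genes the effect differed from that at E9.5, by 3.88, 1.82 and −2.11 (adjusted p = 7.54e-08, 0.000922 and 0.000673). The background at E9.5 also held B6C3F1.

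Of all genes, 795 were higher and 505 lower in E13.5 1Runx1, 101 of them at least 2-fold. The share higher was 61.2%, and 49.3% with quantile normalization and 50.8% with limma-voom on recovered reads. The residual SD of a typical gene was 0.09 at E13.5 and 0.062 at E9.5 and in the liver. The spread shared by all stages may thus make p-values at E13.5 too small. With the E13.5 libraries alone in the fit, 5 genes were called, on 2 residual degrees of freedom.

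Several lists of markers of other cell types lay lower in this comparison. Of 15 hepatocyte genes 1 was higher and 10 were lower, over all genes and adjusted over the list alone, with a median of −1 (camera adjusted p = 1.28e-06, or 0.367 with an estimated correlation); Apoa1 (−1.40) and Fgb (−1.48) were among them. Erythroid genes had 7 of 12 lower, and 11 adjusted over the list alone (median −1.1, camera adjusted p = 6.16e-07, or 0.339 with an estimated correlation), including Gata1 (−0.78), Alas2 (−1.05) and the anion exchanger gene Slc4a1 (−1.31). Macrophage genes had 7 of 18 lower, with 1 higher and 8 lower adjusted over the list alone, including the complement genes C1qa (−0.75) and C1qb (−1.37) and Csf1r (−0.77) (camera adjusted p = 0.000263, or 0.303 with an estimated correlation). Neutrophil and mast cell genes (median −0.97), megakaryocyte genes (−0.19), mesenchymal genes (−0.36) and neural genes (−0.46) lay lower too, at camera adjusted p = 0.0309, 0.0144, 0.0177 and 0.0165, or 0.448, 0.303, 0.453 and 0.471 with an estimated correlation.

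Brain endothelial genes rose in the same comparison, 6 of 11 over all genes and 9 adjusted over the list alone, with a median of 0.66 (camera adjusted p = 6.43e-06, or 0.3 with an estimated correlation). They included the amino acid transporter gene Slc7a5 (0.88) and the Wnt pathway genes Lef1 (0.74) and Apcdd1 (0.73). Interferon-stimulated genes had 8 of 20 higher, and 10 higher and 1 lower adjusted over the list alone (median 0.46, camera adjusted p = 0.000263, or 0.415 with an estimated correlation), among them Gbp3 (0.80), Ifitm3 (0.68) and Isg15 (0.94). Of 24 endothelial identity genes 6 rose, including Cldn5 (0.48), a tight junction gene, and Tek fell (−0.39), with 8 and 2 adjusted over the list alone (camera adjusted p = 0.127). Hemogenic regulators moved both ways: Gata2 (0.65), Lmo2 (0.44), Kit (0.60), Adgrg1 (0.63) and Cd44 (0.97) rose and Nfe2 fell (−0.66), with 5 and 3 adjusted over the list alone (median 0.08, camera adjusted p = 0.519). Of 26 TGFβ targets, Cdkn1a (2.02) and the growth factor gene Hbegf (0.32) rose and Smad7 (−0.87) and Thbs1 (−0.59) fell, with 3 and 4 adjusted over the list alone (median −0.09, camera adjusted p = 0.551).

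With 2 added copies at E13.5, the increases were again in Stat4 (1.94 ± 0.12, adjusted p = 5.43e-05), Itgb3 (1.88 ± 0.13, from 0.862 to 5.88 ± 1.04 RPKM, adjusted p = 0.000176), Ltc4s (1.5 ± 0.18), AI467606 (1.43 ± 0.16) and Lgals9 (0.94 ± 0.08, from 54.4 to 106 ± 2.08 RPKM). Dok2, an adaptor of haematopoietic cells, rose by 1.13, Alox5 by 0.93 and Gprin3 by 1.12. Pcdhgb8 (1.11) and Serpina3g (0.93) were called as well, and had adjusted p = 0.0618 and 0.0615 without the 2Runx1 replicate 2 library. The decreases included erythroid genes, with Gata1 at −0.87, Hemgn at −0.97, the pyruvate kinase gene Pklr at −0.75 and the mitochondrial iron importer Slc25a37 at −0.69 (adjusted p = 0.0572 without 2Runx1 replicate 2). C1qb fell by 1.1 ± 0.09 (adjusted p = 0.00039), Med18, a Mediator subunit gene, by 1.44, the chromatin protein gene Hmgn2 by 0.91, the fibrinogen gene Fgb and the actin gene Acta1 by 0.90 and Serpina6 by 0.97.

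In total 19 genes were higher and 15 lower, against 1642 at an unadjusted p under 0.05. By limma the count of 34 was 0 with the E13.5 libraries alone (772 at an unadjusted p under 0.05), and it was 55 with limma-voom, and 256 and 111 without 2Runx1 replicate 1 and replicate 2. The balance of directions changed between settings, with 147 higher and 109 lower without replicate 1, 29 and 82 without replicate 2, 30 and 119 with no filter, 19 and 36 with limma-voom, and 6 and 9 with the replicate block. Erythroid genes had a median of −0.90, with 1 of 12 lower and 8 adjusted over the list alone (camera adjusted p = 1.47e-08, or 0.303 with an estimated correlation), and hepatocyte genes −0.36, with 1 of 15 lower, and 1 higher and 7 lower adjusted over the list alone (camera adjusted p = 2.4e-05, or 0.407 with an estimated correlation). Of 20 interferon-stimulated genes 0 passed over all genes and 8 were higher adjusted over the list alone (median 0.26, camera adjusted p = 4.33e-05, or 0.383 with an estimated correlation). Hemogenic regulators had 0 of 15 over all genes, but 4 higher (Gata2 0.47, Kit 0.46, Adgrg1 0.56, Cd44 0.67) and 3 lower (Nfe2 −0.53, Gfi1b −0.65, Runx1t1 −0.37) adjusted over the list alone. Of TGFβ targets 0 passed over all genes, with Cdkn1a at 0.83 and adjusted p = 0.0543, and 0.00483 adjusted over the list alone. Endothelial identity genes had 0 of 24 by either adjustment (median 0.05).

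The direct comparison of 2Runx1 with 1Runx1 detected no higher Runx1 level with the second copy: the difference was −0.13 ± 0.10 (95% interval −0.35 to 0.10, adjusted p = 0.503). Other genes did differ, 272 higher and 397 lower with 2 copies. Higher in 2Runx1 were Cdk5rap1 (1.5 ± 0.12, 14.1 ± 0.827 against 4.33 ± 0.494 RPKM), Pcdhgb8 (1.61), the aldo-keto reductase gene Akr1e1 (0.96), and Afp (1.19), Ambp (1.09) and S100a9 (1.42). Lower were Eno1b (−3.50 ± 0.07, 2.72 ± 0.188 against 41.1 ± 1.12 RPKM, adjusted p = 1.97e-09), the translation factor gene Paip1 (−1.97 ± 0.10), Gt(ROSA)26Sor (−1.77 ± 0.11), Ttyh2 (−1.40 ± 0.20), and the MHC genes H2-K1 (−1.88 ± 0.08) and H2-Q1 (−1.48 ± 0.09), whose reads can be shared within their family. The heat shock genes Hspa1a (−1.5) and Hspa1b (−1.57) are near-identical to each other and uncertain, as is the ribosomal RNA gene Rn45s (1.11). Hbb-bh1 (1.71), Fbp1 (1.68), Slc18a1 (1.09), Dnase1l3 (−1.77) and Rbm45 (−1.48) were called, yet varied between replicates, and their adjusted p without the 1Runx1 replicate 1 library was 0.0569 for Hbb-bh1, 0.0819 for Fbp1, 0.075 for Dnase1l3 and 0.108 for Rbm45, and for Slc18a1 0.146 without 1Runx1 replicate 2.

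The share higher among these 669 genes was 40.7%, and 52.1% with quantile normalization. The total was 9 with the E13.5 libraries alone. Hepatocyte genes were higher with 2 copies, 7 of 15 over all genes and 9 higher and 1 lower adjusted over the list alone (median 0.47, camera adjusted p = 5.74e-05, or 0.430 with an estimated correlation). Brain endothelial genes were lower, 2 of 11, and 10 adjusted over the list alone (median −0.35, camera adjusted p = 3.38e-05, or 0.303 with an estimated correlation). Macrophage (0.14), megakaryocyte (0.34), glycolysis (0.12), cell cycle (0.10), venous (0.24) and TGFβ component (0.08) lists had medians above 0, at camera adjusted p = 0.00772, 0.00625, 0.00972, 0.0126, 0.0227 and 0.0415, or 0.407, 0.3, 0.303, 0.471, 0.580 and 0.307 with an estimated correlation. Of the TGFβ targets Fn1, encoding fibronectin, was higher (0.75), and Cdkn1a was 1 of 2 lower (−1.19), with 2 and 3 adjusted over the list alone.

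Both E13.5 contrasts used the same Ctrl library. Besides Runx1 they shared 30 genes called in the same direction. In 100 simulations of unchanged groups with a shared control the average was 0, but unchanged groups yield almost no calls, so that count decides nothing. With Runx1 counted, 18 higher and 13 lower genes were shared, against 1.2 and 0.6 for independent lists. The fold changes correlated at 0.68 across genes, which are not independent replicates, and at 0.67 in the simulations, and their covariance was 0.0406 against 0.0136. The single control could not be split, so part of the excess may come from it. Across stages, E9.5 and E13.5 1Runx1 shared 56 higher genes (6.8 for independent lists) and 11 lower (1.7), E9.5 and E13.5 2Runx1 shared 12 higher (0.2) and 1 lower (0), and E9.5 and the liver shared 33 higher (18.5) and 13 lower (3.3). The liver shared 224 higher (136.2) and 53 lower (41.1) with E13.5 1Runx1, and 10 higher (3.3) and 5 lower (1.2) with E13.5 2Runx1.

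Higher in all 4 comparisons with Ctrl were 9 genes, and 0 were lower in all 4. They were Runx1, AI467606, Itgb3, Stat4, Ltc4s, Dok2, Gem, Def6 and Nfkbie. In the order E9.5, E13.5 1Runx1, E13.5 2Runx1 and liver, Itgb3 changed by 2.08, 1.30, 1.88 and 2.60, Stat4 by 1.95, 1.87, 1.94 and 2.08, and Ltc4s by 1.54, 1.91, 1.5 and 1.34. Dok2 changed by 1.08, 1.22, 1.13 and 1.36, Gem, a small GTPase gene, by 1.03, 1, 0.89 and 2.64, the guanine exchange factor gene Def6 by 1.09, 1.2, 0.83 and 0.52, and the NF-κB inhibitor gene Nfkbie by 0.72, 0.78, 0.67 and 0.63.

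In adult liver endothelium, the increases with 2 added copies included Itgb3, F2rl3, Pla2g7 and Tubb6. Itgb3 rose by 2.60 ± 0.11, from 6.81 ± 0.349 to 46.3 ± 2.64 RPKM (adjusted p = 8.73e-08), and F2rl3, the thrombin receptor PAR4, by 2.55 ± 0.08. Pla2g7, which inactivates platelet-activating factor, rose by 3.02 ± 0.16, from 8 ± 0.133 to 72.0 ± 0.291 RPKM (adjusted p = 4.13e-07), and Tubb6, a β-tubulin gene, by 2.72 ± 0.05, from 13.51 ± 0.0186 to 94.5 ± 2.1 RPKM (adjusted p = 5.93e-10). Gem (2.64), Gdpd3 (2.97), Pilra (2.37) and D17H6S56E-5 (2.48) rose likewise, and Mmp9 by 3.74 ± 0.58 (adjusted p = 0.000833, or 0.107 with limma-voom). Trim12a was listed at 0 in both Ctrl libraries and at 5.68 ± 0.236 RPKM in 2Runx1, and it shares sequence with its family. The largest decreases were in the interferon-inducible genes Ifi44l, from 22.2 ± 3.17 to 0.0109 ± 0.0153 RPKM (−4.51 ± 0.11), and Ifi202b, from 21 ± 1.75 to 0.0242 ± 0.00975 RPKM (−4.43 ± 0.13). The chemokine-binding receptor gene Ackr1 fell by 3.29 ± 0.19, from 191 ± 4.12 to 18.7 ± 0.524 RPKM, Pcp4l1 by 2.82, and the cytidine deaminase gene Cda by 2.98. Ackr1, Pcp4l1 and Ifi202b lie within 2.81 Mb of each other on chromosome 1. The strain background was mixed, and whether it underlies differences of single genes, such as Ifi44l, Ifi202b and Trim12a, was not tested. Sfn (−1.68), Mctp1 (−1.59), Med18 (−1.39), Gpr155 (−1.38) and the immediate early gene Fosb (−1.31) were the other named decreases.

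In the liver 2149 genes were higher and 1021 lower, 255 and 38 of them at least 2-fold. The share higher was 67.8%, and 54.5% with quantile normalization. The total of 3170 was 2019, 1978 and 2027 without Ctrl replicate 1, 2Runx1 replicate 1 and 2Runx1 replicate 2.

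All 22 cell cycle genes rose in the liver, over all genes and adjusted over the list alone, with a median of 1.52 (camera adjusted p = 5.5e-27, or 0.117 with an estimated correlation). The mitotic cyclin genes Ccnb1 and Ccna2 rose by 2.16 ± 0.07 and 1.96, the topoisomerase gene Top2a by 2.00, and Rrm2, a subunit of ribonucleotide reductase, by 1.98. Of 20 arterial genes 9 fell, including the Notch ligand gene Dll4 (−0.88), Hes1 (−0.98), Vegfc (−0.98) and the connexin gene Gja5 (−0.80), while Nrarp (0.72) and Jag2 (0.28) rose, with the same counts adjusted over the list alone (median −0.25, camera adjusted p = 0.000231, or 0.303 with an estimated correlation). Of 10 venous genes 4 rose, including Nr2f2 (0.37) and the chemokine receptor gene Ackr3 (1.62). Stellate cell genes had 6 of 9 lower and 1 higher, and 7 and 1 adjusted over the list alone, with Dcn at −1.12 and the vitamin A esterifying enzyme gene Lrat at −0.80 (camera adjusted p = 0.00177, or 0.3 with an estimated correlation). Immediate early genes had 8 of 16 lower, and 10 adjusted over the list alone, including Egr1 (−0.75) and Dusp1 (−0.61) (camera adjusted p = 3.58e-05, or 0.492 with an estimated correlation). Mesenchymal genes had a median of −0.27 (camera adjusted p = 0.0278, or 0.471 with an estimated correlation).

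Hemogenic regulators in the liver showed 3 of 15 higher, namely Mycn (0.88), Gata2 (0.34) and Meis1 (0.25), and Mecom lower (−0.32), with the same counts adjusted over the list alone (camera adjusted p = 0.936). Of 26 TGFβ targets, Tgfbi (0.56), Pmepa1 (0.53), Bambi (0.40) and Ski (0.21) rose and Hbegf (−0.48), Klf10 (−0.41) and Fn1 (−0.38) fell, 4 and 3 by either adjustment (camera adjusted p = 0.743). Among TGFβ components, the ligand gene Tgfb3 (1.48), Ltbp3 (0.62) and Smad3 (0.43) rose. Endothelial identity genes split into 4 higher, including Plvap (0.69), and 7 lower, including Erg (−0.63) and Cd34 (−0.48), with 5 and 7 adjusted over the list alone (camera adjusted p = 0.139). NF-κB genes had 4 of 19 higher, including Nfkb1 (0.70), and 8 lower, including Icam1 (−0.65). Few blood cell markers passed the test: pan-haematopoietic genes had 1 of 15 higher (Was 1.07) and 2 lower, erythroid genes 0 higher and 2 lower, and megakaryocyte genes 2 of 8 higher, Itga2b (1.04) among them, and 1 lower. Hepatocyte genes had 1 of 15 higher and 1 lower, macrophage genes 2 of 18 higher and 2 lower, and sinusoidal genes 1 of 16 higher and 4 lower.

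**Figure D2:**
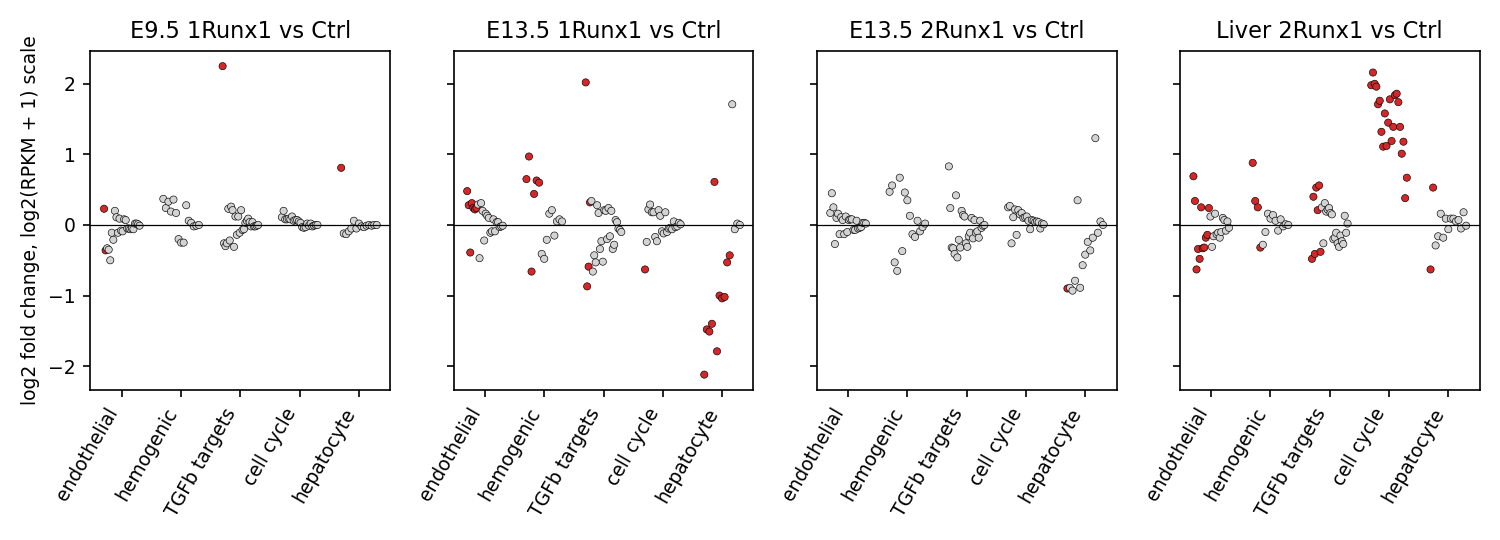
Log2 fold change of each member (points) of 5 of the 27 gene lists in the Runx1 comparisons, with members at an adjusted p under 0.05 over all genes in red; these 5 lists were chosen for the plot after their values were seen. All 22 cell cycle genes lie above 0 in the liver, where their median was 1.52, and the hepatocyte genes lie mostly below 0 in E13.5 1Runx1, where their median was −1.

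Control endothelium of the 3 stages differed in more genes than Runx1 and Ctrl groups did at any stage. From E9.5 to E13.5 the fatty acid binding protein gene Fabp4 rose by 6.04 ± 0.23, from 0.931 to 126 RPKM, with Slc38a5 (5.09) and Rgcc (4.77), while the pluripotency-associated RNA-binding gene Lin28a (−3.95), the glucose transporter gene Slc2a3 (−4.21) and Prtg (−3.66) fell. Afp (5.81) and Alb (4.82), secreted by liver cells, were higher at E13.5, and the placental hormone gene Prl3b1 (−3.36) was lower. In total 2804 genes were higher and 3315 lower at E13.5. Cell cycle genes fell in 17 of 22 cases (median −0.50, camera adjusted p = 1.73e-05, or 0.322 with an estimated correlation), glycolysis genes in 12 of 16 (median −1.2, camera adjusted p = 1.73e-05, or 0.3 with an estimated correlation), and brain endothelial genes rose in 9 of 11 (median 1.57, camera adjusted p = 0.000462, or 0.354 with an estimated correlation). Hepatocyte (11 of 15), erythroid (11 of 12) and macrophage (12 of 18) markers were higher at E13.5 as well. Comparisons with E13.5 Ctrl rest on 1 library, in which Afp was at 78.3 RPKM against 17.5 in 1Runx1 and 41.1 in 2Runx1. Whether these markers came from the endothelial cells was not tested. B6C3F1 and superovulated females were used only at E9.5, so stage coincides with them. TGFβ targets had 10 higher and 3 lower (median 0.27, camera adjusted p = 0.0331, or 0.648 with an estimated correlation).

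In adult liver endothelium against E9.5, Fcgr2b, the inhibitory Fc receptor, was higher by 10.57 and the lectin gene Clec4g by 10.49, reaching 2191 and 6035 RPKM, and Igf2 was lower by −7.88, from 405 to 0.723 RPKM, with H19 (−7.78) and Aplnr (−7.75). Against E13.5 the embryonic globin gene Hbb-y was lower by −9.55 and Itm2a by −7.30, and H2-K1 was higher by 7.69. All 16 sinusoidal genes and all 20 interferon-stimulated genes were higher in the liver than at both embryonic stages, and all 22 cell cycle genes were lower, with medians of −3.62 and −3.06 (camera adjusted p = 3.98e-09 and 2.19e-10, or 0.3 for both with an estimated correlation). Hemogenic regulators had 4 higher and 8 lower against E9.5, and 5 and 10 against E13.5. The counts were 5351 higher and 5359 lower against E9.5, and 5097 and 4847 against E13.5. Runx1 itself differed by 0.31 between E13.5 and E9.5 (adjusted p = 0.061), 0.30 between liver and E9.5 (0.0172) and −0.01 between liver and E13.5 (0.941).

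The effect of 1 copy differed between E13.5 and E9.5 in 284 genes, 146 higher and 138 lower, and the effect of 2 copies differed between liver and E13.5 in 1392 genes, 1029 and 363, where the share higher was 73.9%, and 63.9% with quantile normalization. Both interactions used the single E13.5 Ctrl library. B6C3F1 and superovulated females were used only at E9.5, so the first interaction cannot tell stage apart from them. Between E13.5 and E9.5, hepatocyte genes differed with 0 higher and 7 of 15 lower (10 adjusted over the list alone; camera adjusted p = 3.78e-08, or 0.312 with an estimated correlation), macrophage genes with 6 of 18 lower (9 adjusted over the list alone; camera adjusted p = 2.67e-06, or 0.3 with an estimated correlation) and brain endothelial genes with 3 of 11 higher (9 adjusted over the list alone; camera adjusted p = 3.27e-06, or 0.3 with an estimated correlation). Between liver and E13.5, all 22 cell cycle genes differed upward (median 1.52, camera adjusted p = 1.06e-30, or 0.117 with an estimated correlation) and arterial genes had 6 of 20 lower and 1 higher (camera adjusted p = 0.000356, or 0.304 with an estimated correlation). Over all genes, hemogenic regulators had 0 in the first of these interactions and 1 higher and 1 lower in the second, and TGFβ targets 0, and 3 and 3. The 284 genes became 49 with only the E9.5 and E13.5 libraries, and 50, 39, 167, 47 and 452 without E9.5 Ctrl replicate 1, E9.5 Ctrl replicate 2, E9.5 1Runx1 replicate 1, E9.5 1Runx1 replicate 2 and E13.5 1Runx1 replicate 2. The 1392 became 851 with only the E13.5 and liver libraries, 848 without liver Ctrl replicate 1 and 811 without liver 2Runx1 replicate 2.

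Open chromatin was listed at 99298 peaks in E9.5 Ctrl and 96532 in 1Runx1, at 96537, 100268 and 80857 in E13.5 Ctrl, 1Runx1 and 2Runx1, and at 39019 and 39469 in liver Ctrl and 2Runx1. The liver lists covered 13 and 12.8 Mb and the others 34.7 to 38.5 Mb. Of the liver Ctrl peaks, 79.7% overlapped an E13.5 Ctrl peak and 76.2% an E9.5 one, while 28.3% of E9.5 Ctrl peaks overlapped a liver one. With added Runx1, 14896 peaks (15.4%) were gained and 17336 (17.5%) lost at E9.5, 15234 (15.2%) and 12320 (12.8%) with 1 copy at E13.5, 7821 (9.7%) and 23151 (24.0%) with 2 copies at E13.5, and 12235 (31.0%) and 11769 (30.2%) in the liver. Against 1Runx1, the 2Runx1 list had 5766 gained and 24134 lost peaks. With equal numbers of top-ranked peaks at E13.5, 8888 were gained and 9381 lost with 1 copy, 11930 and 11990 with 2, and 11162 and 10668 in 2Runx1 against 1Runx1. Lists cut to equal length gain and lose nearly equal numbers by construction. These counts thus cannot tell whether the excess of lost peaks with 2 copies came from list length or from closed chromatin. Of the peaks gained at E9.5, 15.4% were gained at E13.5 with 1 copy and 2.0% in the liver. Gained peaks were narrower and weaker than shared ones, with a median width of 152 against 344 bp and a median −log10 q of 5.37 against 24.3 at E9.5. Without peak lists per replicate, no difference between lists could be set against replicate error.

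**Figure D3:**
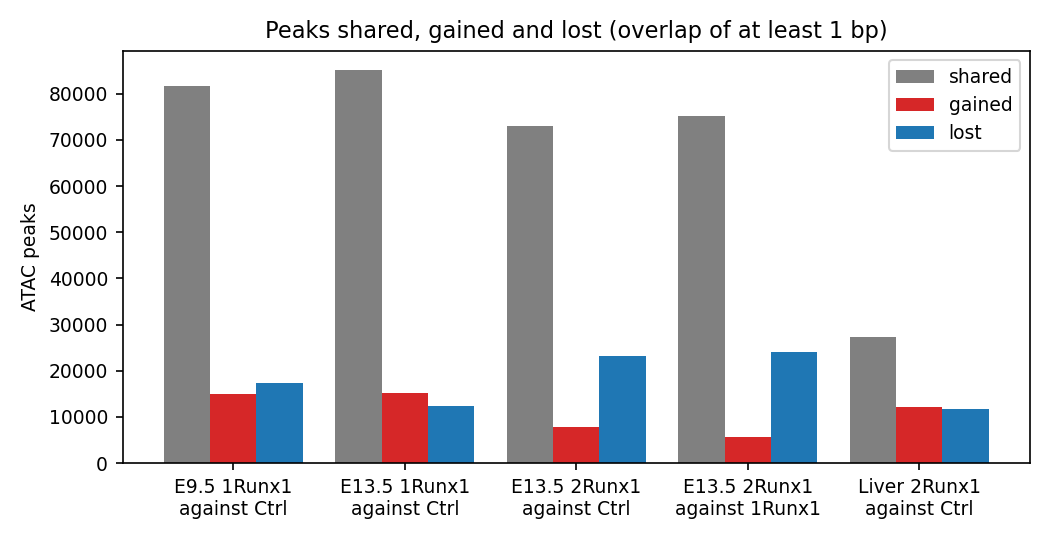
Number of ATAC-seq peaks shared with, gained over and lost from the Ctrl list, or from the 1Runx1 list for E13.5 2Runx1 against 1Runx1. Each group had 1 combined list, and peaks were shared with an overlap of at least 1 bp. Against Ctrl, the gained peaks number 14896 at E9.5, 15234 and 7821 at E13.5 with 1 and 2 copies, and 12235 in the liver. Against 1Runx1, 2Runx1 gained 5766. The lists were of unequal length. With equal numbers of top-ranked peaks, the gains over Ctrl at E13.5 were 8888 and 11930.

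TGFβ target genes of control endothelium had fewer peaks in the liver, whose peak list was also the shortest. Per gene and 10 kb on both sides, they had a median of 6 peaks at E9.5, 5 at E13.5 and 3 in the liver, against 3.79, 3.83 and 2.13 on average in random lists matched on expression. These medians lay at percentiles 99.7, 93.6 and 94.1 of the random lists. With an equal number of top-ranked peaks in each list the medians were all 3, at percentiles 94.5, 92.9 and 94.0, so no difference between stages was seen by that measure. TGFβ components had 9, 8 and 4 peaks (percentiles 100, 100 and 99.8) and hemogenic regulators 7, 8 and 3 (99.5, 99.8 and 91.5). Endothelial identity genes (8, 10 and 5.5) and adhesion genes (9, 9 and 4.5) were at percentile 100 at all 3 stages, while macrophage genes had medians of 1.5, 0.5 and 0, at percentiles 0.1, 0 and 0. Long genes collect more peaks, and against lists matched on gene length too, TGFβ targets were at 99.8, 94.1 and 93.9, components at 99, 95.1 and 96, hemogenic regulators at 99.7, 99.9 and 90.3, and adhesion genes at 88, 85.2 and 95.7, while endothelial identity genes stayed at 100. Within 50 kb of the gene TGFβ targets were at 100, 99.9 and 55.7, so in that window the liver lay lower than the embryonic stages.

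Of the 26 TGFβ targets, 10 had a gained peak at E9.5, 12 and 9 at E13.5 with 1 and 2 copies, and 9 in the liver, and of all genes 36.6%, 37.9%, 23.3% and 27.4% had one. Their medians of 0 peaks decided nothing. By the mean, a measure added after the data were seen, they had 0.85, 0.85, 0.46 and 0.62 gained peaks, against 0.65, 0.7, 0.34 and 0.39 in random lists (percentiles 80.8, 74, 78.9 and 91.6). Within 50 kb of the gene their medians were 2, 2, 1 and 1.5, at percentiles 97.2, 96, 88.3 and 99.9 of lists not matched on length. The collagen IV genes Col4a1 (chromosome 8, 11198423 to 11312889) and Col4a2 had the most among them, with 3, 6, 3 and 4 and with 3, 2, 2 and 2 gained peaks in the 4 comparisons, followed by the integrin gene Itgb5 with 4, 2, 1 and 2. Hemogenic regulators lay at percentiles 92.8, 91.7, 99.5 and 98.6 by the median and 99.3, 71.4, 86.9 and 98.4 by the mean; Mecom (chromosome 3, 29951296 to 30509759) had 12, 6, 2 and 2 gained peaks and Adgrg1 2, 1, 1 and 3. Adhesion genes lay at percentiles 98.1, 100, 100 and 99.7 by the median and 99.9, 100, 100 and 99.9 by the mean, and endothelial identity genes at 99.8, 99, 98.1 and 100 by the mean. Against lists matched on gene length too, the medians of adhesion genes were at 56.6, 95.5, 88.6 and 85.9, inside the central 95% in all 4 comparisons, and those of hemogenic regulators at 92.3, 89.8, 99.5 and 98.4. Within 50 kb adhesion genes were at 100, 100, 87.4 and 74, and hemogenic regulators at 93, 46.4, 83.2 and 72.6.

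H3K4me1 regions at E13.5 numbered 48795 in Ctrl, over 33.4 Mb, and 88344 in 2Runx1, over 88.8 Mb, and 90.9% of Ctrl regions overlapped a 2Runx1 region and 41.9% the other way. With equal numbers of top-ranked regions these shares were 74% and 58.5%. Of the ATAC-seq peaks gained with 2 copies, 41.1% lay in 2Runx1 regions and 16.3% in Ctrl regions. For lost peaks these shares were 36.6% and 16.6%, and for shared peaks 60.4% and 34.1%. With equal numbers of top-ranked regions, 26.5% of gained and 24.1% of lost peaks lay in 2Runx1 regions. The assignment of the 2Runx1 regions to the ChIP libraries rests on labels that appear to be exchanged.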

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

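Of the tests in this part, those of blood cell markers in the liver and of dilution against the median decrease at E13.5 were chosen only after their results were seen. All values are differences of effects on the log2(RPKM + 1) scale from limma's interaction terms with Benjamini-Hochberg adjustment, unless stated otherwise. No group had enough samples for a test of outlying samples. Bootstrap intervals of a list's median were made by resampling the list's members within 1 fit. They treat co-regulated genes as independent and hold no error between libraries.

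The effect of 1 added Runx1 copy differed between E13.5 and E9.5 in 284 genes. Stage cannot be told apart here from background and mating, since B6C3F1 and superovulated females were used only at E9.5. The largest differences upward were in Eno1b (3.88), Mir7688 (2.52; a small RNA gene listed at 0 in E13.5 Ctrl, whose reads may belong to a host transcript), Ttyh2 (2.2), Gt(ROSA)26Sor (1.82) and H2-K1 (1.81), and those downward in S100a9 (−2.17), Cdk5rap1 (−2.11), Afp (−2.11), Ambp (−1.88) and Ppbp (−1.83). Eno1b stood at 86.6 and 86.3 RPKM in E9.5 Ctrl, at 2.3 in E13.5 Ctrl, at 40.3 and 41.9 in E13.5 1Runx1, and at 2.59 and 2.85 in E13.5 2Runx1. Gt(ROSA)26Sor was at 0.763 RPKM in the single E13.5 Ctrl library, 6.65 ± 0.311 in 1Runx1 and 1.25 ± 0.269 in 2Runx1. At E13.5 both genes thus set 1Runx1 apart from Ctrl and 2Runx1, although Runx1 was at 26.3 and 23.9 RPKM with 1 and 2 copies. Their differences did not follow the Runx1 level, and whether strain background underlies them was not tested. S100a9, Afp, Ambp and Ppbp, which are neutrophil, liver and platelet genes, were highest at E13.5 in that 1 Ctrl library, at 9.5, 78.3, 9.74 and 4.64 RPKM.

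At E13.5, 1300 genes were called with 1 copy and 34 with 2, and 669 differed between the 2 groups, although Runx1 itself was 26.3 ± 3.65 RPKM with 1 copy and 23.9 ± 1.75 with 2. Dilution of the 2Runx1 libraries by cells of other types would lower endothelial genes alike and raise markers of the other types. Hepatocyte (median 0.47), megakaryocyte (0.34) and macrophage (0.14) lists lay higher in 2Runx1, at camera adjusted p of 0.43, 0.3 and 0.407 with an estimated correlation, whereas erythroid (−0.06) and pan-haematopoietic (0.06) medians were near 0. The sort would remove blood cells by CD41, CD45 and Ter119. The endothelial identity list had a median of −0.08 (bootstrap interval −0.13 to 0.00), with members from −0.24 to 0.54 (SD 0.18). The median called decrease, −0.35, lay below that list's median by more than this SD (difference −0.28 before rounding). Called decreases are selected for their strength, so their median would lie below that of an unselected list whatever the cause. The difference therefore decides nothing about dilution. The weakest called decrease was −0.15. By the bound set beforehand, a list median above it spoke against dilution, and −0.08 lay above it. That bound left out the members' spread, and −0.15 lay within this SD of the list's median, so no conclusion was drawn from it. For the called decreases, dilution cannot be told apart from other causes, because the list members went both ways. Strain background carried in blocks of the genome may contribute, since the labels name a mixed background. Of the called genes, 15.1% had an adjacent called gene, against 10.4% on average and 14.4% at the 99th percentile of 10000 random lists matched on expression, and the share was 27.3% for 1Runx1 against Ctrl (19.7% on average). The other comparisons with Ctrl lay below the 99th percentile of such lists. Their shares were 5.4% at E9.5 (2.3% on average), 0% for E13.5 2Runx1 (0.5%) and 45.9% in the liver (44.3%). Co-regulated neighbours would give the same excess where it was seen, and an effect of copy number stays open, as untested.

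The effect of 2 copies differed between liver and E13.5 in 1392 genes. Runx1 gained 1.68 more in the liver. The largest differences upward were in Pla2g7 (3.09), Gdpd3 (2.90), Zfp429 (2.47), Trim12a (2.44) and Tubb6 (2.43), and those downward in Ifi202b (−4.81), Ifi44l (−4.58), Ackr1 (−3.41), Pcp4l1 (−2.89) and Cda (−2.12). Ifi202b was at 19.8 and 22.3 RPKM in liver Ctrl and at 0.0314 and 0.0173 in liver 2Runx1. In a span of chromosome 1 from Pcp4l1 to Ifi202b (171173264 to 173982844), chosen after the values were seen, 9 of 47 tested genes were higher and 6 lower in the liver, against 2149 and 1021 of all 12546 genes. Of the liver calls, 45.9% had an adjacent called gene, against 44.3% on average in random lists matched on expression (percentile 92.6). That share does not decide whether the mixed strain background underlies single genes such as Ifi44l and Ifi202b, which was not tested.

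All 22 cell cycle genes were higher in liver 2Runx1, with a median of 1.52. Scaling of the libraries was argued against, as the lower of the medians with quantile normalization and median-of-ratios scaling was 1.41 (bootstrap interval 1.15 to 1.71). A large share of dividing blood cells among the sorted cells, which the sort would remove by CD45 and Ter119, was argued against too: the highest median among 5 blood cell lists was 0.14 (0.00 to 0.20), that of the pan-haematopoietic genes, with −0.05 for erythroid and −0.12 for neutrophil and mast cell genes. A small share cannot be excluded, because the lymphocyte list rested on 2 genes and macrophages were not among the 5 lists. An action of Cre and tamoxifen in the liver cannot be told apart from one of RUNX1, because 0 groups had Cre without an added copy. An effect of RUNX1 on division of these cells remains a hypothesis.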

How the results depend on the processing

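Limma-voom on recovered reads, fry, the mean of peaks and the alternatives of the shared E13.5 response were chosen after the data were seen, and the other alternatives before. In the liver and in the 3 comparisons of Ctrl groups, total counts stayed within 1.5 times under each setting that kept all libraries. Embryonic counts changed with the settings below, whereas the liver libraries alone gave 3316 genes (3170 with all libraries); the cause was not tested. Of the differences of named genes, called or not, quantile normalization left 676 on the same side, weakened 30 and reversed 1 that was not called, median-of-ratios scaling weakened 6, limma-voom 69, no trend 44, the pseudocount 96, no filter 110, the replicate block 120 and the stages alone 204. Over all single libraries left out, calls of named genes weakened in 442 cases, and 2 differences that were not called reversed. Of 260 list tests, 86 passed with the preset correlation and 0 with an estimated one. The planned search for motifs, in whole peaks and with a looser motif, was not run. In the simulation 52% of changes of 0.5 were found at E13.5 with 2 copies. It drew no reads and assumed the same spread at all stages, so it does not bound what depth and spread allowed.

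Totals, higher and lower counts in the stages alone were 37, 29 and 8 for E9.5 1Runx1 (149, 108 and 41 with all libraries), 5, 4 and 1 for E13.5 1Runx1 (1300, 795 and 505), 0, 0 and 0 for E13.5 2Runx1 (34, 19 and 15), 9, 1 and 8 for 2Runx1 against 1Runx1 (669, 272 and 397), 49, 20 and 29 for the E13.5 and E9.5 interaction (284, 146 and 138) and 851, 658 and 193 for the liver and E13.5 interaction (1392, 1029 and 363). The pseudocount of 0.1 gave 18 in all and 4 lower for E13.5 2Runx1, and 147, 82 and 65 for the E13.5 and E9.5 interaction. No filter gave 149, 30 and 119 for E13.5 2Runx1. Quantile normalization gave 23 lower for E13.5 2Runx1 and 213 lower for the E13.5 and E9.5 interaction. Without a trend, 264 were lower in 2Runx1 against 1Runx1 and 97 higher in the E13.5 and E9.5 interaction. Limma-voom gave 800 lower for E13.5 1Runx1, 55 in all and 36 lower for E13.5 2Runx1, and 443 higher for 2Runx1 against 1Runx1.

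With each replicate left out in turn, the counts ran from 41 to 89 for E9.5 1Runx1 (37 to 66 higher, 4 to 23 lower), from 111 to 256 for E13.5 2Runx1 (29 to 147 higher, 82 to 109 lower), and from 1978 to 2185 for the liver (505 to 572 lower). For 2Runx1 against 1Runx1, 178 to 305 were higher. The E13.5 and E9.5 interaction ran from 39 to 452 (19 to 233 higher, 20 to 219 lower) and the liver and E13.5 interaction from 811 to 1583 (647 to 1097 higher, 162 to 548 lower). Runx1 in 2Runx1 against 1Runx1, not called, ran from −0.26 to 0.01 and turned without 1Runx1 replicate 1. Runx1 in liver Ctrl against E13.5 Ctrl, not called, turned to 0.19 with quantile normalization and ran from −0.12 to 0.10 with replicates left out, turning without liver Ctrl replicate 1.

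Replicates share only a number: the correlation of same-numbered libraries was −0.06 at E9.5, −0.05 at E13.5 and 0.11 in the liver. With the number as a block, totals, higher and lower counts were 457, 239 and 218 for E13.5 1Runx1, 15, 6 and 9 for E13.5 2Runx1, 288, 127 and 161 for 2Runx1 against 1Runx1, and 76, 28 and 48 for the E13.5 and E9.5 interaction. E9.5 1Runx1 had 87 in all and 13 lower, and the liver and E13.5 interaction 210 lower. The shared E13.5 response of 30 genes was 13 with the block, 14 with the pseudocount of 0.1, 131 with no filter and 51 with limma-voom.

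For ATAC-seq, a reciprocal overlap of 50% gave 23494 gained and 26260 lost peaks at E9.5, 23943 and 20212 with 1 copy at E13.5, 15616 gained with 2 copies and 13119 gained against 1 copy. Equal numbers of top-ranked peaks gave 8888 gained with 1 copy, 11930 gained and 11990 lost with 2 copies, and 11162 and 10668 against 1 copy. The stricter part of each list gave 4831 and 6123 at E9.5, 5267 and 3614 with 1 copy, 2264 and 9989 with 2 copies, 1163 and 10553 against 1 copy, and 3366 and 3194 in the liver. In H3K4me1, 15170 shared peaks were covered by 50% or more in Ctrl regions, and equal numbers of regions gave 2076 gained and 5582 lost peaks in 2Runx1 regions.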

Other observations

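The list of p53 target genes, its test in the liver, and the count of gained peaks at called genes were chosen only after results were seen. Adhesion and matrix genes, which the report gives for peaks, moved both ways in RNA. In the liver 6 of 22 rose, including Itgb3 (2.60), the laminin receptor gene Itga6 (0.69) and Jam3 (0.58), and 6 fell, including Lamb1 (−0.54), with 8 and 6 adjusted over the list alone. In E13.5 1Runx1 4 rose, Itgb3 (1.30), Cldn5 (0.48), Sparc (0.27) and the tight junction gene Ocln (0.66), with 6 and 1 adjusted over the list alone. Glycolysis and hypoxia genes in the liver split as well, with Eno1 (0.62), Ldha (0.53) and Hk2 (0.47) among 7 of 16 higher and the mitophagy receptor gene Bnip3 (−0.54) among 5 lower. Of the RUNX partners, the binding partner gene Cbfb rose by 0.46 in the liver and the corepressor gene Tle1 fell (−0.42). Oxidative phosphorylation genes had 5 of 17 higher in the liver and 3 in E13.5 1Runx1.

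Peaks were set beside expression at called genes. At E9.5, 45.8% of the higher genes (49 of 107 with a position) had a gained peak, against 36.6% of all genes, and their mean of 0.83 gained peaks lay at percentile 99.3 of random lists matched on expression and length. The lower genes had one in 45% of cases (18 of 40), with a mean of 1.02 at percentile 91.5. In E13.5 1Runx1 the share with a gained peak was 35.5% for higher and 31.8% for lower genes, both below the 37.9% of all genes. The lower genes had a mean of 0.55 against 0.82 in random lists (percentile 0), and the higher genes 0.60 against 0.50 (99.7). In E13.5 2Runx1 the shares were 42.1% of higher (8 of 19) and 13.3% of lower genes (2 of 15), and the means of 0.58 and 0.13, against 0.37 and 0.19 in random lists, lay at percentiles 87.9 and 35.9. In the liver 33.1% of lower and 25.9% of higher genes had a gained peak, against 27.4% of all genes, and the means of 0.53 and 0.36, against 0.41 and 0.36 in random lists, lay at percentiles 100 and 38.1. The shares were not set against random lists.

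The growth arrest gene Cdkn1a led to a look at p53 target genes in the embryonic Runx1 groups. At E9.5 Trp53inp1 (1.32), Ccng1 (1.22), Sesn2 (1.01), Phlda3 (0.98) and Mdm2 (0.59) were higher, and a list was then written, of which 31 members had not been looked at before. Their median was 0.28 at E9.5, with 7 higher and 0 lower (camera adjusted p = 4.66e-12, or 0.00861 with an estimated correlation), 0.19 in E13.5 1Runx1 (0.000173, or 0.0698 with an estimated correlation), 0.12 in E13.5 2Runx1 (0.0179, or 0.144 with an estimated correlation), and −0.17 in 2Runx1 against 1Runx1 (0.00137, or 0.0784 with an estimated correlation). These p-values were adjusted only over the tests of the p53 list, not with the 260 tests of the fixed lists, so the 2 sets are not comparable. For the 31 members at E9.5, the unadjusted camera p with an estimated correlation was 0.00131. The immediate early and dissociation stress list lay higher at E9.5 too (median 0.36, camera adjusted p = 0.00177, or 0.602 with an estimated correlation), but had medians of −0.11 and −0.29 in E13.5 1Runx1 and 2Runx1. Stress of the cells at E9.5 stays open. Scaling of the libraries was argued against, as the lower of the medians under both other scalings at E9.5 was 0.26 (bootstrap interval 0.11 to 0.35). The intervals given here are over list members and hold no error between libraries. An action of Cre and tamoxifen alike in every tissue would raise the median over all members in the liver to the 0.33 of E9.5. It was −0.03 there (−0.16 to 0.01). The livers were taken at an unknown interval after tamoxifen, against 24 hours for embryos, so this value cannot exclude a short-lived response. An action of Cre and tamoxifen in the embryo alone cannot be told apart from one of RUNX1, because 0 groups had Cre without an added copy; a p53 response to either may underlie the pattern and remains a hypothesis.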
